A study of Mus musculus with 8 samples.

How the data were processed

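RNA of mouse telencephalon was measured in 8 samples, 2 arrays for each of 4 groups: basal ganglia +/-, basal ganglia -/-, cortex +/- and cortex -/-. Groups and replicate numbers were taken from the sample titles, in which the numbers are 2 and 3 in each group.

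The deposited values are intensity values, 1 summarised signal per probe set on a linear scale, for 45101 probe sets. The mean of each array with 2% of values trimmed at each end lay between 149.958 and 149.963, so the arrays had been scaled to a common level before deposit. The software and its settings are not given in the sources used here. No detection calls were used, so a low signal is given as a value and not as absence. The lowest signal per array was 0.0266 to 0.0552 and 24.6% to 34.1% of the signals of an array were below 16. Ratios of 3' to 5' control probe sets were 1.19 to 1.34 for actin and 0.649 to 0.768 for Gapdh. Spiked poly-A control RNA differed between groups: the dap control averaged 1834 in BG +/-, 1164 in BG -/-, 876 in Ctx +/- and 336 in Ctx -/-. The 18S 5' probe set averaged 3195, 788, 186 and 112, with single arrays at 1124 and 5265 in BG +/- and at 1126 and 450 in BG -/-.

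Of the probe sets, 64 controls were left out. Of the other 45037, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160, and the symbols name 18193 genes. None of the symbols needed an update through its gene identifier. Chromosomes were looked up by symbol in a RefSeq gene table of assembly GRCm38.p6, used for names and chromosomes only.

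Signals were analysed as log2(signal + 16), without further normalization. The offset means that differences of low genes are understated. Probe sets in the lowest 30% by mean log2 over the 8 arrays were left out, which kept 31526. A linear model of 4 group means was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, and moderated two-sided tests were adjusted by Benjamini-Hochberg over the probe sets kept, with a threshold of 0.05. All groups shared 1 estimate of the spread, with 4 residual and 2.76 prior degrees of freedom. The comparisons were -/- against +/- in each region, the difference of these effects between the regions, and basal ganglia against cortex in each genotype.

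A gene is represented by the probe set that names it alone and has the highest mean log2 over all arrays, which gave 13627 genes. The rule for naming genes was fixed before the data were examined, as were the tests, the gene lists and the alternatives except where stated. Named first are Dlx1, Dlx2, Dlx5 and Dlx6. Then come, for each genotype comparison, the 12 genes with the largest change in each direction among those past the threshold whose arrays did not overlap, and the 8 largest in each direction for the other comparisons. Up to 4 members of each list with the smallest p follow. Of these list members mainly those past the threshold are given. Both genotype effects, as log2 changes or signals, are given for genes named for their difference between regions. These 2 choices were made after the values were seen. Genes with clone names are not named, which leaves out 2 of those ranked among the rises in BG, 1 for the difference between regions, and 1 and 2 for the regions in +/- and -/-. An earlier choice of list members by hand, which in part avoided values that reverse under an alternative, was dropped for the rule above.

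The 23 gene lists came from textbook knowledge of the embryonic telencephalon. They covered the DLX family, GABA synthesis and transport, interneurons from the medial and from the lateral or caudal ganglionic eminence, striatal projection neurons, ventral progenitors, the Notch pathway, radial glia, the cell cycle, cortical glutamatergic neurons, oligodendrocyte lineage, neuron maturation, neurite growth and axon guidance. Lists of red blood cells, endothelium, microglia, meninges, choroid plexus, neighbouring brain, adrenal medulla, immediate early and stress genes and sex-linked genes marked other tissue or sample quality. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists of a comparison. Several members had no single-gene probe set among those kept and were not tested here. Where a list passed, its median, mean and test had the same sign. Of the lists that did not pass, 2 in BG and 5 in Ctx had signs that differed.

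The fit was tested on simulated arrays of 31526 probe sets. Each probe set was drawn independently around its mean over all arrays, with its residual spread pooled over the groups. For each comparison, 67 probe sets were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. For BG, the fit recovered 0% of those changed by 0.5, 25.4% of those changed by 1 and 65.2% of those changed by 2. For Ctx it recovered 31.3% and 72.7% of the latter 2, and for the difference between regions 31.8% of those changed by 2. Far more probe sets passed in the BG data than were changed here, so these shares need not hold there. Of 100 unchanged lists, camera gave p under 0.05 for 2, 3 and 5 in these comparisons. Simulated probe sets were uncorrelated, so these counts say nothing of lists with correlated members.

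The alternatives were another offset, quantile normalization, centring on the median, another filter on low signals, only the arrays compared, the replicate number as a block, another variance model, another threshold, a minimum change, and leaving out each array in turn. Chosen after seeing the data were fits without genes on X and Y and with only probe sets of 1 gene symbol. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.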

Results

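Gene expression was measured on oligonucleotide arrays in mouse telencephalon from animals carrying Dlx1/2 mutations. Dlx1 and Dlx2 are neighbouring homeobox transcription factors of the ventral forebrain. The labels describe RNA from basal ganglia (BG) and from cortex (Ctx), each with the genotype +/- or -/-, which makes 4 groups with n = 2 arrays each and 8 arrays in all. A source label also names blood and adrenal medulla, which conflicts with the tissue given for each sample, so genes of both were examined as a check. Arrays of the same group correlated at 0.973 to 0.982 (Pearson, across probe sets, log2 scale) and arrays of different groups at 0.930 to 0.977. Ctx +/- replicate 3 correlated at 0.977 with each Ctx -/- array, above its 0.973 with Ctx +/- replicate 2. By these correlations the genotypes were thus not clearly apart in Ctx. The median signal per array lay between 37.9 and 51.5. Control RNAs differed between the groups: the spiked dap control averaged 1834 in BG +/-, 1164 in BG -/-, 876 in Ctx +/- and 336 in Ctx -/-. The 5' probe set of 18S ribosomal RNA averaged 3195, 788, 186 and 112 in the same order. Its BG genotypes were not clearly apart, with arrays at 1124 and 5265 in BG +/- and at 1126 and 450 in BG -/-. With 2 arrays per group, the number of arrays limits the precision of every comparison, and nothing in the labels says that the arrays of a group came from separate animals. The p-values then measure only the spread between these arrays, which may be technical.

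The targeted genes were lower in every array labelled -/-. Dlx1 averaged 1234 ± 3.34 (SD, n = 2) signal units in BG +/- and 9.57 ± 8.34 in BG -/-, and 138 ± 1.28 in Ctx +/- against 2.08 ± 0.482 in Ctx -/-. Dlx2 averaged 323 ± 50.3 in BG +/- and 8.62 ± 0.0812 in BG -/-, and 55.3 ± 0.0262 in Ctx +/- against 9.35 ± 3.76 in Ctx -/-. Where the probes of both genes lie relative to the deleted sequence is not known here. Of the related genes Dlx5 and Dlx6, which were not targeted, Dlx5 was at 719 and 706 in the BG +/- arrays and at 65.6 and 71.1 in the BG -/- arrays. Dlx6 was at 169 and 140 in BG +/- and at 20.6 and 19.8 in BG -/-. In Ctx, Dlx5 was at 93.9 and 92.3 in +/- and at 1.82 and 17.7 in -/-, and Dlx6 at 25.3 and 2.17 in +/- and at 2.03 and 1.29 in -/-.

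The first comparison asked which genes differ between the genotypes in the basal ganglia. Beyond the DLX genes, 10 of 24 genes of striatal projection neurons fell in BG -/-, 1 rose and 13 did not pass (limma camera, adjusted p = 0.000463, and adjusted p = 0.161 with an estimated correlation). Slc32a1, the vesicular GABA transporter, fell by 3.22 ± 0.20 (SE, log2 scale), from signals of 474 and 403 to 24.2 and 42.9, while its other, dimmer probe set, at 0.20 ± 0.29, did not pass. The retinoid receptors Rxrg and Rarb fell, with changes of -2.82 ± 0.42 and -2.40 ± 0.12. Pak3, an X-linked kinase gene that regulates the actin cytoskeleton and neurite growth, rose by 1.34 ± 0.11, from 1069 and 1029 to 2706 and 2669, and all 4 of its probe sets rose. Npy and Sst, neuropeptides of interneurons, rose by 1.11 ± 0.13 and 0.66 ± 0.13.

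Among the DLX genes that fell, the log2 change was -5.65 ± 0.21 for Dlx1, -4.80 ± 0.18 for its antisense transcript Dlx1as, -4.21 ± 0.20 for Dlx6os1, -3.77 ± 0.16 for Dlx2, -3.11 ± 0.27 for Dlx5 and -2.23 ± 0.35 for Dlx6. The strand that each probe set of an antisense pair detects was not examined here. The largest falls also included those of Slc32a1, Rxrg and Rarb and, on chromosome Y, of Eif2s3y at -3.81 ± 0.18, Uty at -2.50 ± 0.25 and Kdm5d at -2.46 ± 0.26. The largest rises were those of Xist at 5.50 ± 0.13, the transcript that coats the inactive X chromosome, and Mid1 at 2.68 ± 0.13, also on X. Leaving aside 2 genes with clone names, they were followed by the transcription factor Ebf3 at 2.23 ± 0.15, the long non-coding RNA Rmst at 2.03 ± 0.18, the zinc finger gene Zfp950 at 1.95 ± 0.22 and the ubiquitin ligase Marchf1 at 1.93 ± 0.15. Arpp21 rose by 1.92 ± 0.15 on the probe set that represents it, while another of its probe sets fell by 0.86 ± 0.15. The calcitonin receptor Calcr rose by 1.63 ± 0.20, the DNA damage kinase Atr by 1.62 ± 0.16 and Gsx1, a homeobox gene of ventral progenitors, by 1.61 ± 0.36. By the rule of selection, only genes for which both arrays of one genotype lay beyond both arrays of the other were ranked by size.

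Members of each gene list are counted by the probe set that represents the gene, and other probe sets are named after their values were seen. Some members passed in BG only on another probe set. Of these, Slit2, Nrp1 and Unc5c (axon guidance), Map2 and Ncam1 (neuron maturation), Tnc (radial glia), Zeb2 (MGE) and Cnr1 (striatal) rose. Foxo1 (striatal), Meis2 (lateral or caudal eminence), Mcm7 (cell cycle) and Stmn1 (neurite growth) fell. Those of further lists are given below. Of 7 DLX family genes tested, 6 fell and none rose (limma camera, adjusted p = 5.30e-08, and adjusted p = 0.0813 with an estimated correlation). Of the 24 striatal projection neuron genes, the member that rose was Arpp21, and adjusted over the list alone 11 fell and 2 rose. The members that fell included the transcription factors Foxp1 at -1.70 ± 0.14, Ebf1 at -1.23 ± 0.12 and Six3 at -1.21 ± 0.17. Of 28 axon guidance and migration genes, 5 rose, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.00817, and adjusted p = 0.161 with an estimated correlation). These included the netrin receptors Dcc at 0.90 ± 0.12 and Unc5d at 0.67 ± 0.14, the ephrin receptor Epha3 at 0.75 ± 0.11 and Nrg3 at 0.59 ± 0.12.

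Genes of interneurons went both ways in BG. Of 16 genes of interneurons from the medial ganglionic eminence (MGE), 3 rose and 5 fell (camera adjusted p = 0.544), with Zic1 at 0.92 ± 0.13, the chemokine receptor Cxcr4 at -1.49 ± 0.14 and Lhx8 at -1.06 ± 0.15. Of 13 genes of interneurons from the lateral or caudal eminence, 2 fell, Htr3a at -1.51 ± 0.29 and Sp8 at -0.87 ± 0.13, and adjusted over the list alone 3 fell (camera adjusted p = 0.262). Of 7 genes of GABA synthesis and transport, Slc32a1 alone passed (camera adjusted p = 0.445). Of 14 ventral progenitor transcription factors, 3 rose, namely Gsx1, Otx2 at 1.35 ± 0.27 and Id2 at 1.15 ± 0.12, and 1 fell, Six3 (camera adjusted p = 0.271). Adjusted over the list alone, 4 of them rose and 2 fell.

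Of 29 cell cycle genes, 4 rose and 3 fell, and adjusted over the list alone 6 rose and 13 fell (camera adjusted p = 0.154), with Cenpf at 0.78 ± 0.11, Kif11 at 0.74 ± 0.14, Top2a at 0.64 ± 0.12 and Cdk1 at -0.87 ± 0.14. Of 22 cortical glutamatergic genes, 1 rose, the vesicular glutamate transporter Slc17a6 at 1.04 ± 0.16, and 3 fell, Neurog1 at -0.92 ± 0.17, Fezf2 at -0.68 ± 0.13 and Neurog2 at -0.56 ± 0.13 (camera adjusted p = 0.452). Adjusted over the list alone, 4 of that list rose and 3 fell, and 6 further members passed on another of their probe sets. Of 22 neuron maturation genes, 4 rose, the X-linked Dcx at 0.93 ± 0.13, Scn2a at 0.89 ± 0.13, Snap25 at 0.81 ± 0.12 and Elavl4 at 0.68 ± 0.13, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.328). Of 17 radial glia genes, 2 rose, Ednrb at 1.08 ± 0.12 and Ptprz1 at 0.75 ± 0.13, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.445). Of 20 Notch pathway genes, 1 rose, Notch2 at 0.60 ± 0.14 (-0.0067 with the mean of all its probe sets), and adjusted over the list alone none did (camera adjusted p = 0.154). Of 18 neurite growth and cytoskeleton regulators, 1 rose, Pak3 (camera adjusted p = 0.464), and of 11 oligodendrocyte lineage genes none passed (camera adjusted p = 0.392), although another probe set of Pdgfra rose by 1.09 ± 0.14 (limma adjusted p = 0.00916).

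Among markers of other cell types, 1 of 6 red blood cell genes fell in BG -/-, the embryonic globin Hbb-y at -0.98 ± 0.13, and adjusted over the list alone 5 fell (camera adjusted p = 0.0134, and adjusted p = 0.204 with an estimated correlation). Of 14 endothelial and mural genes, Rgs5 rose by 0.97 ± 0.12 (camera adjusted p = 0.977), and of 9 meningeal and fibroblast genes, Fbln1 fell by 0.62 ± 0.14 (camera adjusted p = 0.154). Of 9 genes of the diencephalon and other neighbouring brain, 2 rose, Otp at 1.06 ± 0.15 and Lhx9 at 0.58 ± 0.14 (camera adjusted p = 0.0853). None of 11 microglia, 8 choroid plexus, 7 adrenal medulla or 12 immediate early and stress genes passed, with camera adjusted p of 0.786, 0.655, 0.879 and 0.391, although another probe set of Ttr fell by 0.98 ± 0.19 (limma adjusted p = 0.0284). All 4 sex-linked genes tested passed, 1 higher and 3 lower (camera adjusted p = 0.154).

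In all, 3070 of 31526 probe sets passed adjusted p = 0.05 in BG (limma with Benjamini-Hochberg), 2366 higher and 704 lower in -/-. At an unadjusted p under 0.05 there were 8905. Counted by genes, 649 rose and 416 fell of 13627 tested. With each array centred on its median, which moved the median log2 change of all probe sets from 0.01 to -0.10, the share of higher calls went from 77.1% to 57.4%. The groups did not overlap for 59.97% of the probe sets, against 33.3% by chance. The count was 475 without BG +/- replicate 2, 701 without BG +/- replicate 3, 138 without BG -/- replicate 2, 113 without BG -/- replicate 3, and 1578 without either Ctx -/- array. All arrays of one genotype carried the sex-linked pattern opposite to that of the other, so sex and genotype were not separated.

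**Figure D1:**
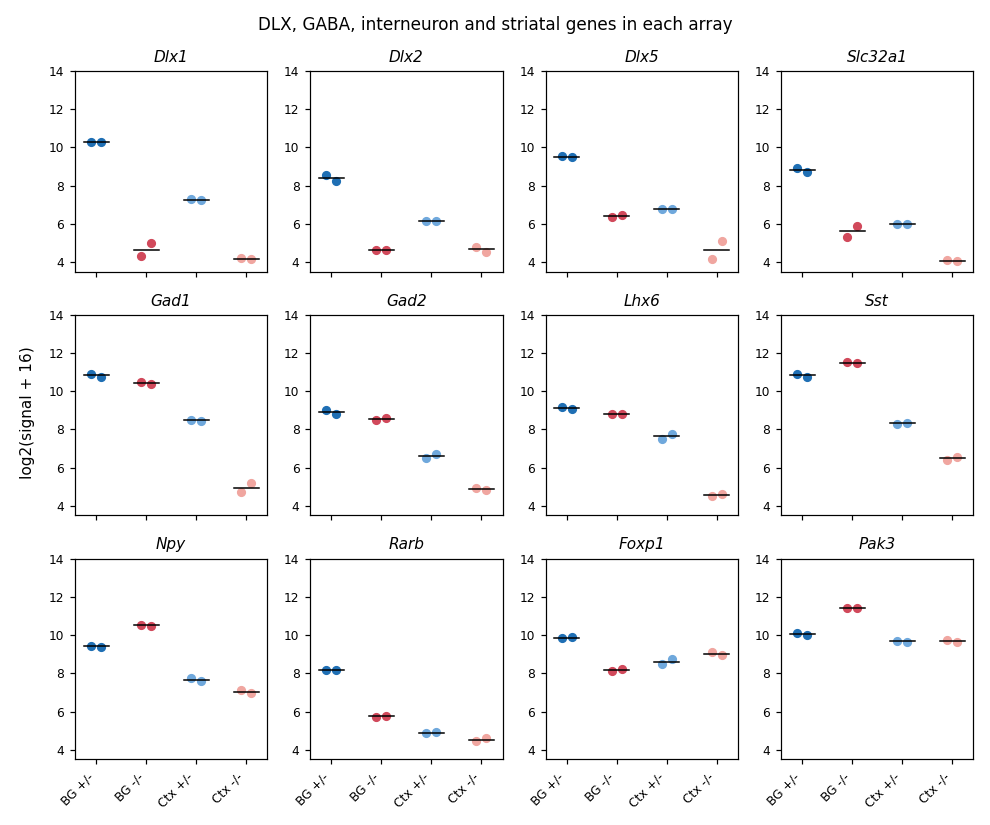
Each panel plots log2(signal + 16) of 1 gene, with a point per array and a line at the mean of the 2 arrays of each group. Dlx1, Dlx2, Dlx5 and Slc32a1 were lower in both -/- arrays than in both +/- arrays of each region, Gad1 was at 10.1 and 20.3 in Ctx -/- and at 1427 and 1298 in BG -/-, and Pak3 was highest in the BG -/- arrays at signals of 2706 and 2669.

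The second comparison asked the same of the cortex. In Ctx -/-, the genes that fell included Gad1, Lhx6 and Sst, which GABA-producing interneurons express. Gad1, which encodes the main GABA-synthesising enzyme, fell by 3.55 ± 0.18 on the log2 scale (limma with Benjamini-Hochberg, adjusted p = 0.000833), from signals of 350 and 338 to 10.1 and 20.3, while its other, dimmer probe set, at -1.29 ± 0.20, did not pass (adjusted p = 0.0958). Lhx6, a transcription factor of interneurons from the MGE, fell by 3.05 ± 0.14 (adjusted p = 0.000462), and the neuropeptide Sst by 1.82 ± 0.13 (adjusted p = 0.00394). The largest fall was that of Ttr, the transthyretin gene that marks choroid plexus, at -9.54 ± 0.21, from 11634 and 13605 to 1.11 and 0.701. Few genes rose, led by Xist at 4.90 ± 0.13 and Mid1 at 1.60 ± 0.13.

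Of the DLX genes, Dlx1 at -3.09 ± 0.21, Dlx1as at -2.01 ± 0.18 and Dlx6os1 at -1.65 ± 0.20 fell, as did Dlx2 from a mean signal of 55.3 to 9.35, whereas Dlx5 at -2.16 ± 0.27 and Dlx6 at -0.63 ± 0.35 did not pass (limma adjusted p = 0.0525 and 0.611). Thus 4 of 7 DLX family genes fell, and 5 adjusted over the list alone (camera adjusted p = 8.54e-11). Of 7 genes of GABA synthesis and transport, 3 fell, Gad1, Slc32a1 at -1.89 ± 0.20 and Gad2 at -1.74 ± 0.14 (camera adjusted p = 6.52e-06, and adjusted p = 0.0976 with an estimated correlation). The other probe set of Slc32a1, at -0.44 ± 0.29, and that of Gad2, at -0.43 ± 0.20, did not pass. Of 16 MGE-derived interneuron genes, 4 fell, Lhx6, Maf at -2.46 ± 0.22, Nxph1 at -2.03 ± 0.19 and Sst, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 8.54e-11). The DLX, MGE and choroid plexus calls also passed with an estimated correlation, at adjusted p = 0.0234, 0.0234 and 0.0296. None of 13 genes of interneurons from the lateral or caudal eminence passed, and 3 were lower adjusted over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.405 with an estimated correlation).

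Of 8 choroid plexus genes, 2 fell in Ctx, Ttr and the potassium channel subunit Kcne2 at -2.73 ± 0.23, and 6 adjusted over the list alone (camera adjusted p = 5.33e-10). Another probe set of a further member, Clic6, fell by 2.56 ± 0.30. None of 11 microglia genes passed over all probe sets and 3 were higher adjusted over the list alone (camera adjusted p = 0.000402, and adjusted p = 0.0843 with an estimated correlation). None of 9 meningeal genes passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.00318, and adjusted p = 0.0976 with an estimated correlation). None of 6 red blood cell genes passed and 1 was lower adjusted over the list alone (camera adjusted p = 0.00878, and adjusted p = 0.111 with an estimated correlation). The 4 sex-linked genes all passed, with Eif2s3y at -4.27 ± 0.18, Uty at -3.16 ± 0.25, Kdm5d at -2.92 ± 0.26 and Xist higher (camera adjusted p = 0.00619, and adjusted p = 0.111 with an estimated correlation). By the probe sets that represent them, no member passed in the lists of striatal, ventral progenitor, Notch, radial glia, cell cycle, cortical glutamatergic, oligodendrocyte, neuron maturation, neurite growth, axon guidance, endothelial, neighbouring brain, adrenal and stress genes, and none of these lists passed camera in Ctx. Another probe set of Dcx, a neuron maturation gene, rose by 1.16 ± 0.14 (limma adjusted p = 0.0436), and another of Nfia, a glutamatergic list member, fell by 1.53 ± 0.12 (limma adjusted p = 0.00642). Adjusted over the list alone, 1 ventral progenitor gene was lower and 1 neuron maturation gene higher, and none of the others passed. The smallest of their adjusted p was 0.0600, for striatal genes.

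In Ctx, 71 probe sets passed (limma with Benjamini-Hochberg), 15 higher and 56 lower in -/-, and 3050 at an unadjusted p under 0.05. By genes, each counted by the probe set that represents it, 3 rose and 25 fell. The gene that rose besides Xist and Mid1 was Raly, at 1.16 ± 0.15, and the neurexophilin gene Nxph2 fell by 2.84 ± 0.32. The groups did not overlap for 39.4% of the probe sets, against 33.3% by chance. Leaving out any 1 of the 8 arrays lowered the count: 33 without either BG +/- array, 39 without either BG -/- array or Ctx +/- replicate 3, 19 without Ctx +/- replicate 2, 23 without Ctx -/- replicate 2 and 22 without Ctx -/- replicate 3. The +/- and -/- arrays differed in sex-linked genes here as well.

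**Figure D2:**
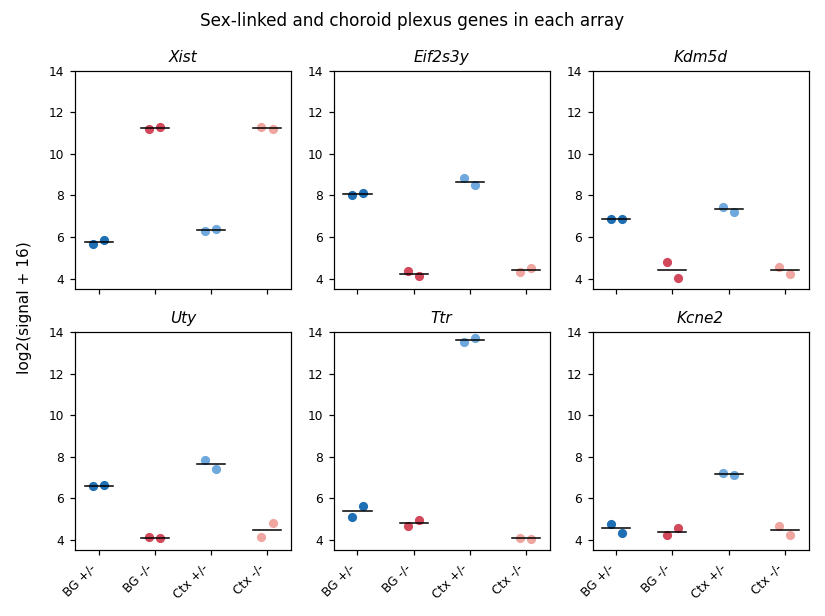
Each panel plots log2(signal + 16) of 1 gene, with a point per array and a line at the mean of the 2 arrays of each group. Xist was high and Eif2s3y, Kdm5d and Uty were low in all -/- arrays, and Ttr and Kcne2 were high in the Ctx +/- arrays alone.

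The third comparison tested whether the genotype effect itself differed between the regions. The change was more negative in Ctx for Gad1, Gad2, Lhx6 and Sst, which interneurons express, and more negative in BG for the transcription factor Foxp1. The log2 change in BG minus that in Ctx was 3.14 ± 0.25 for Gad1 (limma with Benjamini-Hochberg, adjusted p = 0.0211), 2.74 ± 0.20 for Lhx6 (adjusted p = 0.0161), 2.48 ± 0.18 for Sst (adjusted p = 0.0161) and 1.40 ± 0.20 for Gad2 (adjusted p = 0.0471). On the other, dimmer probe sets it was 1.09 ± 0.28 for Gad1, 0.91 ± 0.23 for Lhx6 and 0.36 ± 0.28 for Gad2, none of which passed. In BG alone, Gad1 was at -0.41 ± 0.18, Gad2 at -0.34 ± 0.14, Lhx6 at -0.31 ± 0.14 and Nxph1 at -0.14 ± 0.19, none of which passed. The difference was -2.13 ± 0.20 for Foxp1, with a Ctx change of 0.43 ± 0.14 that did not pass. For Rarb it was -2.04 ± 0.17, but Rarb was at 13.2 and 14.1 in Ctx +/- and at 5.82 and 8.73 in Ctx -/-, below the offset of 16, so a fall in Ctx was hardly measurable.

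The difference was also positive for Ttr at 8.98 ± 0.29, Otx2 at 2.77 ± 0.38, Kcne2 at 2.56 ± 0.32, Fancm at 2.11 ± 0.30, Nxph1 at 1.88 ± 0.28, Npy at 1.71 ± 0.18, Arpp21 at 1.57 ± 0.21 and Pak3 at 1.33 ± 0.16. Another probe set of Arpp21 went the other way, at -1.03 ± 0.22, and did not pass. In Ctx, Pak3 changed by 0.02 ± 0.11, Otx2 by -1.42 ± 0.27, Fancm by -0.82 ± 0.21, Npy by -0.61 ± 0.13 and Arpp21 by 0.36 ± 0.15. None of these Ctx changes passed in limma. In BG, Fancm changed by 1.29 ± 0.21, Otx2 rose by 1.35 ± 0.27, and Kcne2, which did not pass there, changed by -0.17 ± 0.23. The difference was negative for Dlx1as at -2.80 ± 0.25, Dlx1 at -2.56 ± 0.30, Dlx6os1 at -2.56 ± 0.28, Dlx2 at -2.28 ± 0.22, the Rac activator Tiam2 at -1.84 ± 0.18 and the retinoic acid binding protein gene Crabp1 at -1.73 ± 0.19. For Dlx5 at -0.96 ± 0.39 and Dlx6 at -1.60 ± 0.49 it did not pass (adjusted p = 0.270 and 0.178), and with log2(signal + 1) the value of Dlx5 was 0.33. Tiam2 changed by -1.79 ± 0.13 in BG and 0.05 ± 0.13 in Ctx, and Crabp1 by -1.67 ± 0.14 and 0.06 ± 0.14. Dlx1, Dlx1as and Dlx2 averaged less than the offset of 16 in both -/- groups. Dlx6os1 averaged less than it in Ctx -/-, at 13.5, and Kcne2 lay below it in all BG arrays. Ttr was near it in BG, at 18.6 and 34.3 in +/- and at 9.52 and 15.2 in -/-. The differences of these genes, for Dlx6os1 in part, therefore follow the signal of the +/- arrays and the offset, and do not compare relative changes.

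Of 16 MGE-derived genes, 4 had a positive difference that passed, and adjusted over the list alone 4 a positive and 2 a negative one (camera adjusted p = 0.000685, and adjusted p = 0.0835 with an estimated correlation), and of 7 GABA genes 2 did, and adjusted over the list alone 2 positive and 1 negative (0.0369, and adjusted p = 0.298 with an estimated correlation). Of 24 striatal genes, 2 had a negative and 1 a positive difference, and adjusted over the list alone 10 a negative and 1 a positive one (camera adjusted p = 2.16e-06, and adjusted p = 0.0701 with an estimated correlation). The choroid plexus list had 2 positive differences of 8, and 6 adjusted over the list alone (camera adjusted p = 3.29e-05, and adjusted p = 0.0835 with an estimated correlation). Of the DLX genes, 4 of 7 had a negative difference, and 5 adjusted over the list alone (camera adjusted p = 2.27e-06, and adjusted p = 0.0701 with an estimated correlation). These 2 lists hold the genes whose differences do not compare relative changes, Ttr and Kcne2 in the former and Dlx1, Dlx1as, Dlx2 and Dlx6os1 in the latter. In all 11 of the 23 lists passed camera for this difference and 0 of them with an estimated correlation. Those not yet named were ventral progenitor, Notch, cell cycle, axon guidance, neighbouring brain and sex-linked genes (camera adjusted p of 0.0345 to 0.0484). By the representing probe sets, no member of these lists passed except Otx2. The sex-linked list, a check on the samples, passed at 0.0369 although its genes changed the same way in both regions. The other list calls are to be read with that in mind. In total 181 probe sets passed, 163 with a positive and 18 with a negative difference, and 5569 at an unadjusted p under 0.05. With log2(signal + 1), 3 passed. The share of positive differences was 90.1%, and 80.0% with each array centred on its median. The count was 3 without either BG -/- array or Ctx -/- replicate 2 and 4 without any 1 of the other 5 arrays, and Ttr was the 1 gene named here that passed under all alternatives tried.

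**Figure D3:**
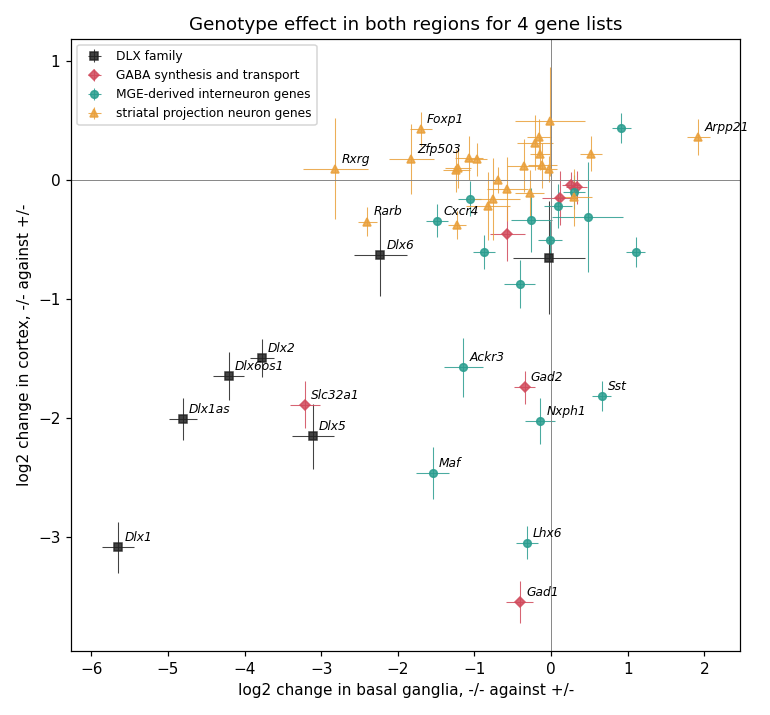
The log2 change (-/- against +/-) in basal ganglia is on the horizontal axis and that in cortex on the vertical axis, with a point per gene, bars of 1 SE and a symbol for each of 4 gene lists. Gad1, Lhx6, Nxph1 and Gad2 lie low on the vertical axis near 0 on the horizontal one, while Foxp1 at -1.70 in basal ganglia lies near 0 on the vertical one, as does Rarb at -2.40, whose cortex signals were all below the offset of 16.

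The remaining comparisons set BG against Ctx within each genotype. In +/-, 5 of 7 genes of GABA synthesis and transport were higher in BG and 1 was lower, also over the list alone (camera adjusted p = 0.00706, and adjusted p = 0.152 with an estimated correlation). Isl1 was higher by 6.07 ± 0.16 on the log2 scale, the tachykinin gene Tac1 by 5.06 ± 0.29, Lhx8 by 4.77 ± 0.15, Zfp503 by 4.34 ± 0.29, Zfhx3 by 4.09 ± 0.17, Rxrg by 4.03 ± 0.42, Resp18 by 3.87 ± 0.18 and Ebf1 by 3.78 ± 0.12. Dlx1 was higher by 3.03 ± 0.21, Dlx5 by 2.74 ± 0.27, Dlx6 by 2.63 ± 0.35, Dlx2 by 2.24 ± 0.16 and Gad1 by 2.34 ± 0.18. Lower in BG were Ttr at -8.24 ± 0.21, Sla at -4.00 ± 0.15, Cntn2 at -3.49 ± 0.17, Dct at -3.30 ± 0.24, Neurod6 at -3.03 ± 0.15, Mfap4 at -2.99 ± 0.22 and Fezf2 at -2.90 ± 0.13.

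Of 22 cortical glutamatergic genes, 16 were lower and 1 higher in BG +/-, and adjusted over the list alone 19 and 1 (camera adjusted p = 1.24e-13, and adjusted p = 0.0710 with an estimated correlation). Of 24 striatal genes 14 were higher and 3 lower, also over the list alone (0.000230, and adjusted p = 0.0710 with an estimated correlation), and of 16 MGE-derived genes 10 were higher and 2 lower, and adjusted over the list alone 11 and 2 (0.000487, and adjusted p = 0.0710 with an estimated correlation). Markers of red blood cells and microglia were also higher in BG +/-, with 4 of 6 and 5 of 11 genes past the threshold (camera adjusted p = 0.00527 and 0.00879, and adjusted p = 0.0985 and 0.102 with an estimated correlation). In all 15 of the 23 lists passed camera, and 0 with an estimated correlation. A total of 7518 probe sets passed (limma with Benjamini-Hochberg), 3489 higher and 4029 lower in BG, against 3902 without BG +/- replicate 2 and 3898 without BG +/- replicate 3. More were higher than lower without Ctx +/- replicate 2, at 3797 and 3151, and with each array centred on its median, at 3904 and 3710.

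In -/-, 6 of 7 genes of GABA synthesis and transport were higher in BG and 1 was lower, also over the list alone (camera adjusted p = 0.000562, and adjusted p = 0.147 with an estimated correlation). Gad1 was higher in BG by 5.48 ± 0.18, Sst by 4.99 ± 0.13, Lhx6 by 4.21 ± 0.14 and Npy by 3.47 ± 0.13, beside Isl1 at 5.56 ± 0.16, Tac1 at 4.46 ± 0.29, Pbx3 at 4.32 ± 0.12 and Thsd7a at 4.28 ± 0.21. Dlx5 was higher by 1.78 ± 0.27, whereas Dlx1 at 0.46 ± 0.21, Dlx2 at -0.03 ± 0.16 and Dlx6 at 1.03 ± 0.35 did not pass (limma adjusted p = 0.179, 0.899 and 0.0848). Lower in BG -/- were Tiam2 at -3.76 ± 0.13, Fezf2 at -3.68 ± 0.13, Mfap4 at -3.40 ± 0.22, Nr4a3 at -3.31 ± 0.20, Cntn2 at -3.09 ± 0.17, Rspo3 at -2.99 ± 0.24 and Sla at -2.96 ± 0.15. Of 16 MGE-derived genes 12 were higher and 2 lower in BG -/-, and adjusted over the list alone 13 and 2 (camera adjusted p = 4.52e-06, and adjusted p = 0.0637 with an estimated correlation), and of 22 cortical glutamatergic genes 14 were lower and 1 higher, and adjusted over the list alone 16 and 1 (2.21e-11, and adjusted p = 0.0637 with an estimated correlation). In all 11 of the 23 lists passed camera, and 0 with an estimated correlation.

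In -/- 5438 probe sets passed (limma with Benjamini-Hochberg), 3361 higher and 2077 lower in BG. The share of higher calls, 61.8%, became 50.4% with quantile normalization and 48.6% with each array centred on its median. The count was 1896 without BG -/- replicate 2, 1974 without BG -/- replicate 3, 2049 without Ctx -/- replicate 2 and 2165 without Ctx -/- replicate 3.

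The estimated genotype effects in the 2 regions, which share no array, correlated weakly across genes. The labels do not say whether both regions came from the same animals. Most genes passed in neither region, so noise lowers the correlation, and a low value does not show that the effects were unrelated. Over 13627 genes, which are not independent replicates, Pearson's r between the log2 changes was 0.205 and Spearman's rho 0.171, and r was 0.131 without Ctx +/- replicate 3. Genes lower in both regions on the probe set that represents them numbered 11, where independent lists would share 0.763, and included Dlx1, Dlx2, Slc32a1, Maf and Nxph2. Genes higher in both numbered 2, Xist and Mid1, against 0.143. Both comparisons used the same estimate of the spread of a probe set, so their calls were not independent and some excess may be built in. Sst and Rbms3 passed in opposite directions, rising in BG and falling in Ctx. Without genes on X and Y, a choice made after seeing the data, r was 0.173 and 8 genes were lower in both, against 0.675.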

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

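The tests of explanations given here were chosen only after the result was seen, except the test of array scaling by quantile normalization. The test of the difference between regions was planned.

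A test of the difference itself showed that the genotype effect differed between basal ganglia and cortex for 181 probe sets. Among the genes named for it, the log2 change in BG minus that in Ctx was -2.80 for Dlx1as, -2.56 for Dlx1, -2.56 for Dlx6os1, -2.28 for Dlx2, -2.13 for Foxp1, -2.04 for Rarb, -1.84 for Tiam2 and -1.73 for Crabp1. It was 8.98 for Ttr, 3.14 for Gad1, 2.77 for Otx2, 2.74 for Lhx6, 2.56 for Kcne2, 2.48 for Sst, 2.11 for Fancm, 1.88 for Nxph1, 1.71 for Npy, 1.57 for Arpp21, 1.40 for Gad2 and 1.33 for Pak3. Dlx1 (9.57 in BG and 2.08 in Ctx), Dlx2 (8.62 and 9.35) and Dlx1as (5.03 and 14.2) had mean -/- signals below the offset of 16. Dlx6os1 had one in Ctx alone, at 13.5. Rarb was below the offset in all Ctx arrays (means of 13.7 in +/- and 7.27 in -/-), and Kcne2 in all BG arrays. For these genes the difference depends on the starting signal and the offset, and does not show that the relative change differed. The same limit holds for Ttr, which in BG was near the offset, at 18.6 and 34.3 in +/- and at 9.52 and 15.2 in -/-. With log2(signal + 1), 3 probe sets passed for the difference in place of 181.

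Xist was higher and 3 Y-linked genes were lower in -/- in both regions, and in 8 of 8 arrays these 4 genes followed the genotype, consistent with RNA of males in the +/- arrays and of females in the -/- arrays. Of the 1058 called genes with a known chromosome, 93.4% were on autosomes. With 445 X-linked and few Y-linked genes tested, X and Y could not have made up most of these calls in any case. The share therefore decides nothing about sex. X-linked genes were over-represented among those that rose in BG, at 58 of 445 against 584 of 13149 others (Fisher's exact test, two-sided, p = 1.52e-12). In Ctx, the same 57 genes without Xist had a median change 0.0891 times that in BG (95% bootstrap interval 0.0480 to 0.144). They were chosen by their BG change, which favours a low ratio. Over all X-linked genes without Xist, the median was 0.0571 in BG and 0.0002 in Ctx, against -0.0806 and -0.0319 for autosomal genes. X-linked genes thus lay above autosomal ones in both regions, and Mid1 and probe sets of Chic1 and Dcx rose in both. For the 57 genes, a sex effect shared by both regions is argued against as the whole cause of the excess, but not as a part of it. Because 0 genotypes hold arrays of both sexes, sex and genotype cannot be told apart for autosomal genes.

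More probe sets rose than fell in BG -/-. The scaling of the arrays as the whole cause is argued against, since 70.6% of the calls were still higher after quantile normalization, over the 65% set beforehand, but centring each array on its median left 57.4%. A rule that also weighed the centred share was tried once both shares were known and then dropped, and under it the question would stay open. Noise of dim probe sets as the whole cause is argued against by the 6305 brightest probe sets, where 64.2% of 902 calls were higher. The exact 95% interval, 61.0% to 67.3%, treats probe sets as independent, which they need not be. Over 5 classes of mean signal from dim to bright, the shares were 70.3%, 84.0%, 85.9%, 82.5% and 64.2%. The excess was thus smallest in the brightest class and largest in the middle one, so a part played by signal level stays open. Shares by class were not tested with each array centred on its median. Probe sets with no gene symbol rose more often than those with 1 symbol at matched signal (odds ratio 3.67, 95% interval 3.33 to 4.05). More RNA of unannotated sequence in the BG -/- samples thus remains a candidate for part of the excess, whether through the genotype or the RNA preparation. The excess was not confined to such probe sets, since among those with 1 symbol alone 1545 were higher and 589 lower (72.4% higher).

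Choroid plexus genes were low in Ctx -/-. Of 8 members tested, 7 were lower in both -/- arrays than in both +/- arrays, which restates the pattern and decides no explanation. Ttr was at 11634 and 13605 in the Ctx +/- arrays and at most 34.3 in any BG array, and 0 of the Ctx -/- arrays exceeded that level. Choroid plexus tissue present in the cortex +/- samples and nearly absent from the cortex -/- samples, and a loss of choroid plexus expression in mutant embryos, cannot be told apart, because no array is known to hold choroid plexus of -/- embryos.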

How the results depend on the processing

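The fits without genes on X and Y and with only probe sets of 1 gene symbol were chosen after seeing the data, and all other alternatives before. Counts of probe sets past the threshold (3070 in BG, 71 in Ctx and 181 for the difference between regions) depended on the settings far more than the directions did. In the same order they were 4969, 146 and 907 with log2(signal + 64), 5962, 227 and 1906 with a variance trend and robust estimation, 5613, 122 and 935 at adjusted p = 0.10, and 4786, 112 and 1033 with the lowest 50% left out. With log2(signal + 1), Ctx had 41 and the difference 3. Without a filter BG had 1761 and the difference 10, and with only the 4 arrays compared BG had 1024 and Ctx 24. Centring on the median gave 75 for the difference, probe sets of 1 symbol 45, and a log2 change of at least 1 gave 923 in BG. For BG against Ctx in +/- the count was 3466 with only the 4 arrays compared and 2635 at a log2 change of at least 1, and in -/- it was 8757 at adjusted p = 0.10 and 2325 at a log2 change of at least 1. Fewer arrays or residual degrees of freedom, more tests and a changed threshold account for some of these by construction, and the cause of the others was not tested.

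Leaving out 1 array at a time gave 113 to 3415 in BG, 19 to 39 in Ctx, 3 to 4 for the difference, 3898 to 6948 and 1896 to 6592 between regions in +/- and -/-, and r of 0.131 to 0.221 between the genotype effects. A lone array is then assumed to vary like the other groups. With the replicate number as a block the counts were 2002 in BG, 36 in Ctx and 4 for the difference. Deviations of arrays with the same number correlated at -0.03 to 0.02, so the numbers are not taken to pair the arrays. The block added the microglia list for the difference and changed no other list call there or in the genotype comparisons.

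Named genes past the threshold were checked under the alternatives that include the gene, except the raised threshold and the minimum change. Genes on X and Y are outside 1 of these alternatives, and some low genes are outside others. With the lowest 50% left out, 58 of 68 named values in BG and 24 of 31 in Ctx were covered. Genes passing under all that include them were 16 of 62 in BG, 5 of 20 in Ctx and 1 of 20 for the difference. Between regions they were 72 of 92 in +/- and 57 of 76 in -/-. Those in BG included Dlx1, Dlx2, Slc32a1, Rarb, Foxp1 and Pak3, and those in Ctx were Gad1, Lhx6, Ttr, Xist and Eif2s3y. In BG, 44 of the 62 lost the call without BG -/- replicate 3, 42 without BG -/- replicate 2, 34 without BG +/- replicate 2 and 32 without BG +/- replicate 3. No named gene reversed under quantile normalization or centring. Notch2 reversed with the mean of all its probe sets, to -0.0067 in BG and 0.22 for BG against Ctx in +/-. Over all 498 values of genes that the naming rule takes, named in the text or not, 25 reversed under some alternative, 2 of the 272 that had passed and 23 of the 226 that had not. The other reversals of named values were of values that had not passed: Dlx5 for the difference at 0.33 with log2(signal + 1), Dlx2 between regions in -/- at 0.12 without Ctx -/- replicate 2 (-0.19 without replicate 3), Kcne2 in BG at 0.066 without BG +/- replicate 2 and 0.0092 without BG -/- replicate 2 (-0.40 without BG +/- replicate 3), and in Ctx Crabp1 at -0.0802 without Ctx +/- replicate 3 (0.19 without replicate 2), Tiam2 at -0.0625 without Ctx +/- replicate 2 (0.16 without replicate 3), and Pak3 at -0.0386 without Ctx -/- replicate 2 (0.076 without replicate 3) and -0.047 with the mean of its probe sets. The cause was not tested. Of the lists past camera, 0 of 4 in BG, 3 of 9 in Ctx and 0 of 11 for the difference passed with an estimated correlation. Signals near the offset of 16 limit what can be said of genes that are low in a group.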

Other observations

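Genes with a probe set called in the same direction in both regions were often on chromosome 2, which carries Dlx1 and Dlx2. This count was chosen after the values were seen. Of 14 such autosomal genes 7 were on chromosome 2. Without Dlx1, Dlx1as and Dlx2, the mutated locus, there were 4 of 11, against 1091 of 13138 autosomal genes tested (Fisher's exact test, two-sided, p = 0.00971), a p that the choice after seeing makes too small. They include Nxph2, Slc32a1, Sema6d and Trp53bp1. A pair of the Trp53bp1 probe sets fell in BG, by 2.35 ± 0.16 and 2.08 ± 0.15 on the log2 scale, and fell in Ctx, by 2.92 ± 0.16 and 2.39 ± 0.15, while its other 4 probe sets did not pass in either region.

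Among 318 zinc finger (Zfp) genes tested in BG, 43 rose and 5 fell, a group singled out after its values were seen and not tested for enrichment.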
